A study of Arabidopsis thaliana with 24 samples.

How the data were processed

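Messenger RNA of Arabidopsis thaliana Col-0 roots and shoots was sequenced after mock treatment or inoculation with Fusarium sp. strain K-23 (K23), with 0 or 50 mM NaCl. Per the labels, seedlings stood 7 days on 0.5x MS medium, were moved to plant nutrition medium, received 50 µl of water or of a spore solution, and were harvested after 7 days with the fungus. RNA was extracted with phenol and chloroform, and polyA RNA was made into NEBNext Ultra libraries. There were 8 groups of 3 libraries, 24 in all, each with its own column of values. The hour of harvest, the strand protocol and whether replicates were separate cultures are not given in the sources used here, so the p-values measure the spread between these samples. Without the strand, genes that overlap on opposite strands are uncertain, as are close relatives such as the LHCB and PDF1.2 families.

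Samples were grouped by the labels alone. The titles of the 3 mock root samples at 0 mM NaCl read like those of an unrelated histone lactylation assay, whereas their descriptions, source, tissue, treatment and organism name mock roots; they were grouped by the description. In the values, these 3 libraries correlated at 0.911 to 0.968 with other root libraries and at most at 0.733 with shoot libraries.

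The authors deposited FPKM values, that is fragments per kilobase of the file's gene length and per 1e6 of an effective library size, for 33068 genes. The submitters' processing notes name CASAVA, HISAT2 2.0.5, HTSeq 0.6.1 and the TAIR10 build without saying what each did; further steps are not given in the sources used here. FPKM times the deposited gene length was a whole multiple of one step per library for 100% of values within 0.05 of a whole number, so the reads per gene were recovered from it. The libraries held 18.8 to 41.7 M recovered reads (median 24.2 M, 24.5 M in roots and 23.8 M in shoots), with 20785 to 24194 genes detected and 3.3% to 10.2% of reads in the 10 largest genes. The authors' effective library size differed from the recovered total by a factor of 0.722 to 1.15 (geometric mean 1.093 in roots and 0.925 in shoots); the method is not given in the sources used here. Because of the 2 different mean factors, differences of responses were compared between tissues rather than levels, except in the check for shoot tissue in a root sample, whose shoot shares carry this uncertainty. Gene positions were checked against the TAIR10.1 annotation: 32548 loci matched, and 99.95% had the same start and end. Gene symbols came from the deposited table or that annotation.

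Values were taken as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 12 libraries of a tissue were tested, 19651 in roots and 19055 in shoots. The 12 libraries of a tissue were fitted in one limma model with a mean per group and empirical Bayes moderation with trend (R 4.3.3, limma 3.58.1), and 5 contrasts were tested per tissue: K23 against mock at 0 and at 50 mM, salt against no salt in mock and in K23 plants, and the interaction. P-values were two-sided and adjusted by Benjamini and Hochberg over the genes of the tissue, with a threshold of 0.05. Differences of responses between tissues were tested in one fit of all 24 libraries over 17618 genes. Correlations of responses were taken across genes and carry no p-value. PR1 and PDF1.2 were below the filter in roots, as were NRT2.1, HKT1 and the root hair list in shoots. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.

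Before the data were examined, 23 gene lists with 341 genes were fixed: jasmonate, ethylene and jasmonate defence, salicylate, immune signalling, tryptophan and camalexin, indole glucosinolate, aliphatic glucosinolate, ABA and osmotic, ion transport, auxin response, auxin synthesis and transport, photosynthesis, nitrate, phosphate starvation, iron deficiency, sulfur limitation, suberin, root hair, oxidative detoxification, hypoxia, senescence, circadian and reference genes. All 341 genes were found. Lists were tested with camera at its preset correlation of 0.01 between genes, adjusted over all lists and contrasts of a tissue; members passing were also counted after adjustment over the list alone. Of 115 root and 110 shoot pairs of list and comparison, 41 and 33 were called. When the correlation was estimated from the residuals none was called, with a lowest adjusted p of 0.132 in roots and 0.522 in shoots, so the list calls hold for the preset correlation only. The rotation test fry kept 15 of 41 root calls and 22 of 33 shoot calls.

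The grouping, the main tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined. Genes to be named were the 10 largest up and 10 largest down per fungus comparison with a mean of at least 2 FPKM in the higher group and no overlap between the groups, 6 and 6 per salt comparison, 5 and 5 per interaction, at most 2 up and 2 down without a symbol, up to 4 passing members of each list, the reference genes, and PR1, PDF1.2, PAD3, RD29A, RD29B, NRT2.1, HKT1 and GH3.3. Of the genes eligible under the rule, those printed are mainly ones whose call was kept in all alternatives. Alternatives chosen beforehand were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, quantile normalization, median-of-ratios scaling, moderation without trend or with robust trend, the replicate number as a block, only the 2 groups compared in the fit, library weights for interactions and tissue comparisons, leaving out each library of a comparison, and for lists an estimated correlation and fry. Added after the data had been seen were voom on the recovered reads, library weights for the 8 simple comparisons, leaving out a library of another group, leave-one-out for tissue comparisons and correlations, and the simulation of unchanged groups for the correlation of mean effects. Lists of 9 morning and 6 evening clock output genes and of 13 touch and wound genes were also added later, the first of them before its values were looked at.

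The tests were tested on simulated data in which reads were drawn from the mean and spread of each gene and the library sizes, with 200 changed genes. At a true 2-fold change the recovered share was 50%, 49%, 49% and 49% in roots (K23 at 0 mM, K23 at 50 mM, salt in mock, salt in K23) and 52%, 52%, 53% and 58% in shoots; at 4-fold it was 79%, 86%, 80% and 78%, and 79%, 79%, 79% and 85%. False calls were 3.7%, 2.9%, 3.7% and 2.3% of calls in roots and 8.4%, 7.1%, 5% and 4.7% in shoots, and no changed gene was called with the wrong sign. With camera, an unchanged list had an unadjusted p of 0.0254 for salt in mock roots and of at least 0.0774 in the other comparisons. Genes were drawn independently, whereas a single axis held 51.1% of the real spread within groups in roots and 35.8% in shoots. These rates may therefore not hold for the real calls. Within groups, libraries correlated at 0.924 to 0.987, and no 2 libraries were copies of each other. No value column was left out.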

Results

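Roots of Col-0 seedlings grown for 7 days with Fusarium sp. strain K-23 (K23 from here) held more transcript of genes such as CYP71A12, PAD3 and CYP81F2 than mock roots. At 0 mM NaCl, CYP71A12, which makes indole acetonitrile from its oxime, rose 13.1-fold to 148 ± 73.5 FPKM from 10.9 ± 7.69 (mean ± SD of 3 libraries; adjusted p = 0.00145). PAD3, the last enzyme of camalexin synthesis, rose 10.5-fold to 31.5 ± 15.1 FPKM from 2.08 ± 1.26 (adjusted p = 0.000845). FOX1, an oxidase of the indole cyanogenic branch, rose 9.18-fold (77.2 ± 46.4 against 7.15 ± 4.03 FPKM). CYP81F2, which hydroxylates indole glucosinolates, rose 8.91-fold (74.5 ± 35.3 against 7.10 ± 2.22 FPKM). IGMT2, which methylates the product of CYP81F2, rose 6.68-fold to 83.2 ± 17.1 FPKM from 12.1 ± 4.74. PEN2, a myrosinase of pathogen defence, rose 2.46-fold to 65.1 ± 10.6 FPKM from 25.7 ± 2.49. MYB122, a regulator of indole glucosinolate genes, rose 7.09-fold (log2 2.83, standard error 0.32, adjusted p = 0.00145). Outside this pathway, the extensin-like gene AT1G26240 rose 14.5-fold (45.4 ± 23.1 against 2.45 ± 2.48 FPKM), the chitinase gene CHI 10.4-fold (53.5 ± 34.2 against 4.35 ± 3.47 FPKM), the secreted lipase gene GLIP1 9.95-fold and the glutathione transferase gene GSTU12 7.99-fold (12.05 ± 2.02 against 0.624 ± 0.158 FPKM). Falls were smaller. The B-box gene BBX29 fell 3.99-fold to 0.646 ± 0.0748 FPKM from 5.77 ± 2.15. The histone gene HTR11 fell 3.15-fold to 3.00 ± 0.634 FPKM from 11.6 ± 2.08. The clock gene RVE8 fell 2.24-fold to 1.83 ± 0.586 FPKM from 5.29 ± 0.872. Folds are ratios of FPKM + 1 on the log2 scale, so they understate changes of genes with low values. In limma, 1376 of 19651 genes passed (949 up, 427 down) and 465 of them by at least 2-fold. The count was 781 with only the 2 groups in the fit, 5296 with library weights, and 295, 472, 589 and 359 without mock 0 mM replicate 3, replicate 2, replicate 1 and K23 0 mM replicate 3.

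Of the 18 tryptophan and camalexin genes in K23 roots at 0 mM, 10 rose, 0 fell and 8 did not pass, and 16 rose when adjusted over the list alone (median log2 1.07, camera adjusted p = 1.1e-10, and adjusted p = 0.441 with an estimated correlation). Of 12 indole glucosinolate genes, 5 rose and 1 fell, with 9 up and 2 down adjusted over the list alone (median log2 0.78, adjusted p = 0.000408, 0.441 with an estimated correlation). The immune signalling list had 6 of 22 genes up and none down, 9 up when adjusted over the list alone (median log2 0.56, adjusted p = 0.00357, 0.592 with an estimated correlation). Iron deficiency genes included PDR9, a coumarin exporter, up 3.297-fold to 38.0 ± 8.95 FPKM from 10.8 ± 2.73; 3 of 18 rose, 5 when adjusted over the list alone (median log2 0.42, adjusted p = 0.0138, 0.441 with an estimated correlation). Sulfur limitation genes had 1 of 7 up, the APS reductase gene APR3 (2.53-fold, 117 ± 27.5 against 44.99 ± 5.53 FPKM), and 4 up when adjusted over the list alone (median log2 0.70, adjusted p = 0.00551, 0.52 with an estimated correlation). Of 5 root hair genes 2 rose, 4 when adjusted over the list alone (median log2 0.96, adjusted p = 0.00804, 0.538 with an estimated correlation). The salicylate list had 0 of 12 genes up or down, 2 up when adjusted over the list alone (median log2 0.36, adjusted p = 0.034, 0.592 with an estimated correlation), and the hypoxia list had 1 of 10 up, 2 when adjusted over the list alone (median log2 0.62, adjusted p = 0.0299, 0.616 with an estimated correlation). Aliphatic glucosinolate genes were the 1 list called down, with 0 of 10 genes passing on their own and 0 adjusted over the list alone (median log2 -0.58, adjusted p = 0.0248, 0.629 with an estimated correlation). The other lists were not called by camera: suberin (median log2 0.72, adjusted p = 0.0936), ion transport (0.19, 0.0809), ABA and osmotic genes (0.23, 0.558), nitrate (0.53, 0.279), jasmonate (-0.21, 0.432), ethylene and jasmonate defence (-0.04, 0.86), auxin response (0.23, 0.199) and oxidative detoxification (0.01, 0.245). In the last of these GSTU24 rose 6.86-fold (90.4 ± 16 against 12.3 ± 2.24 FPKM), and in the auxin response list the conjugating enzyme gene GH3.2 rose 3.65-fold (8.97 ± 2.02 against 1.73 ± 0.533 FPKM). Photosynthesis (-0.12, 0.347), senescence (0.38, 0.087), circadian (-0.30, 0.161) and reference genes (0.00, 0.898) were not called either; auxin synthesis and transport genes had a median of -0.04 but a mean of 0.14 (0.897), and phosphate starvation genes a median of 0.14 but a mean of -0.02 (0.946).

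At 50 mM NaCl many of these genes, such as CYP71A12 and PAD3, rose in K23 roots as well. CYP82C2, which hydroxylates an indole carbonyl nitrile, rose 44.9-fold to 73.3 ± 21.8 FPKM from 0.653 ± 0.505 (log2 5.49, standard error 0.72, adjusted p = 0.00141). CYP71A12 rose 30.5-fold to 375 ± 68.7 FPKM from 11.3 ± 2.19. FOX2 rose 29.6-fold to 74.0 ± 11.5 FPKM from 1.62 ± 0.851. FOX1 rose 24.5-fold to 122 ± 20.05 FPKM from 4.06 ± 1.104. CYP81F2 rose 21.9-fold (94.4 ± 8.03 against 3.54 ± 1.55 FPKM), IGMT4 16.8-fold (121 ± 10.6 against 6.48 ± 2.34 FPKM), IGMT2 14.3-fold (103 ± 7.02 against 6.47 ± 2.11 FPKM) and PAD3 7.84-fold (111 ± 26.7 against 13.04 ± 0.968 FPKM). MYB51, a regulator of indole glucosinolate synthesis, rose 6.33-fold to 61.1 ± 3.14 FPKM from 9.09 ± 3.01. GSTF6, linked to camalexin synthesis, rose 15.8-fold to 844 ± 122 FPKM from 53.8 ± 16.6. The NAC gene JUB1 rose 16.4-fold (28.8 ± 5.83 against 0.794 ± 0.104 FPKM). PROPEP3, precursor of a danger peptide, rose 9.91-fold (21.4 ± 2.41 against 1.31 ± 0.596 FPKM). The xyloglucan endotransglucosylase gene XTH7 fell 7.16-fold to 21.7 ± 15.2 FPKM from 137 ± 25.03. The morning-phased genes LNK1 and CDF3 fell 5.33-fold (3.87 ± 1.89 against 24.6 ± 7.80 FPKM) and 3.91-fold (10.5 ± 3.26 against 42.9 ± 1.33 FPKM). ICS1, which starts salicylate synthesis, fell 1.94-fold to 8.69 ± 2.25 FPKM from 17.5 ± 1.90. Reads of close relatives such as the IGMT and CYP71A genes can be shared between them, and how such reads were assigned is not given in the sources used here. In limma, 825 of 19651 genes passed (522 up, 303 down; 463 by at least 2-fold). The count was 525 with only the 2 groups, 3338 with library weights, 366 without mock 50 mM replicate 1, 391 and 477 without K23 50 mM replicates 3 and 2, and 1286 without K23 0 mM replicate 1.

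**Figure D1:**
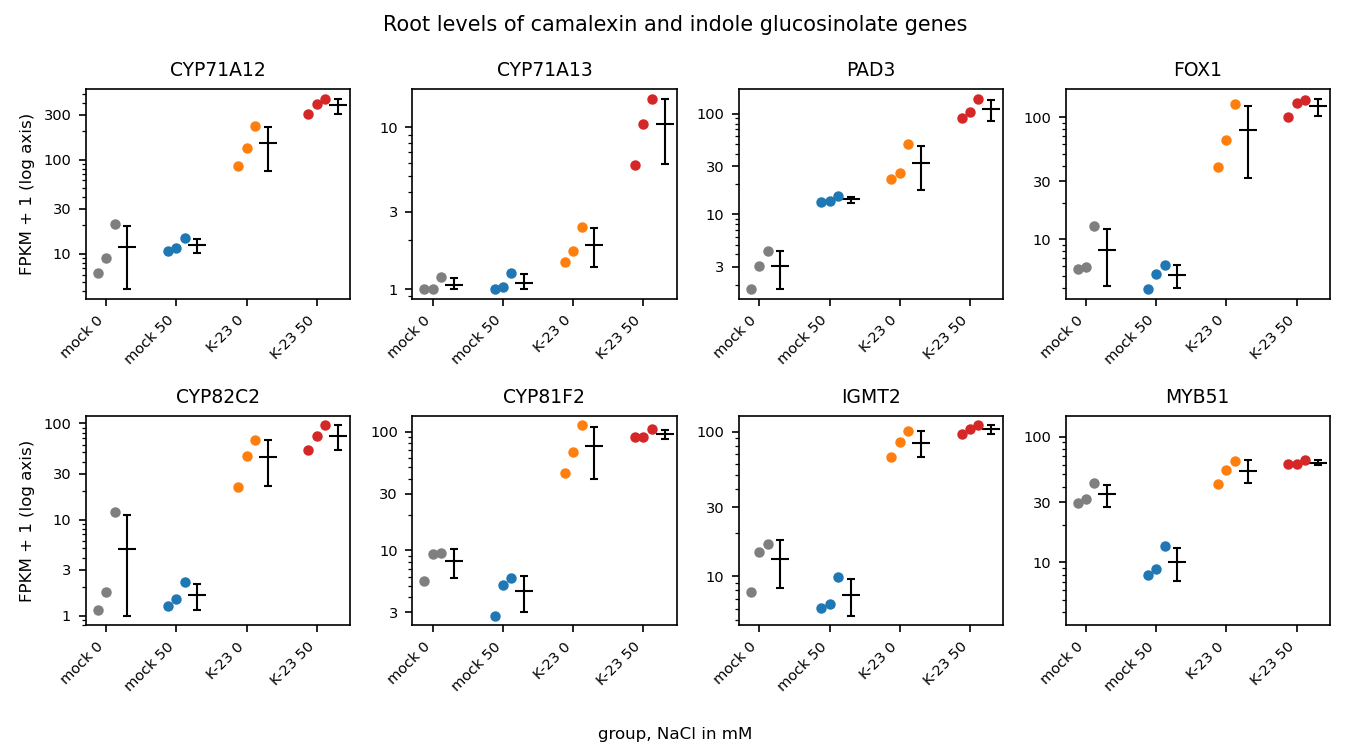
Indole and camalexin pathway genes in roots, 4 groups on the horizontal axis and FPKM + 1 on a logarithmic vertical axis, 3 libraries per group; dash and bar give mean ± SD, with the lower end at 0 FPKM where the SD exceeds the mean. CYP71A12 reached 375 ± 68.7 FPKM with K23 and 50 mM NaCl.

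At 50 mM, 15 of 18 tryptophan and camalexin genes rose and none fell, and all 18 rose when adjusted over the list alone (median log2 2.12, camera adjusted p = 2.4e-31, and adjusted p = 0.179 with an estimated correlation). Of 12 indole glucosinolate genes 9 rose and 1 fell, 11 and 1 when adjusted over the list alone (median log2 1.27, adjusted p = 4.22e-14, 0.132 with an estimated correlation). The ethylene and jasmonate defence list had 1 of 12 genes up, the defensin gene PDF1.1 (3.16-fold, adjusted p = 0.00584), also 1 when adjusted over the list alone (median log2 0.47, adjusted p = 0.00661, 0.538 with an estimated correlation). Immune signalling had 2 of 22 up, among them WRKY30 (4.70-fold), and 3 when adjusted over the list alone (median log2 0.26, adjusted p = 0.000408, 0.538 with an estimated correlation). Senescence genes had 2 of 9 up, SEN1 (AT4G35770) 7.50-fold to 37.2 ± 14.7 FPKM from 3.92 ± 1.27 and SAG13 6.69-fold, with 4 up and 1 down adjusted over the list alone (median log2 0.54, adjusted p = 0.00293, 0.441 with an estimated correlation). Called down were aliphatic glucosinolate genes (1 of 10 up, none down, but 1 up and 5 down adjusted over the list alone; median log2 -0.71, adjusted p = 0.00608, 0.592 with an estimated correlation) and photosynthesis genes (0 up and 2 down of 28, 3 down adjusted over the list alone; median log2 -0.40, adjusted p = 0.000954, 0.696 with an estimated correlation). ABA and osmotic genes were also called down, with 1 of 25 down, and 1 up and 2 down adjusted over the list alone (median log2 -0.65, adjusted p = 0.00636, 0.676 with an estimated correlation). Nitrate genes had 0 of 10 passing and 1 down adjusted over the list alone (median log2 -0.57, adjusted p = 0.00956, 0.578 with an estimated correlation). Root hair genes had 0 of 5 passing and 2 down adjusted over the list alone (median log2 -0.84, adjusted p = 0.0191, 0.578 with an estimated correlation). The high-affinity nitrate transporter gene NRT2.1 (log2 -0.67, adjusted p = 0.483), the sodium transporter gene HKT1 (-0.63, 0.425), RD29A (-1.04, 0.665) and GH3.3 (0.31, 0.548) did not pass. Salicylate (median log2 0.14, adjusted p = 0.593), jasmonate (-0.13, 0.641), iron deficiency (0.24, 0.101), sulfur limitation (-0.23, 0.352), auxin synthesis and transport (-0.25, 0.0667) and phosphate starvation genes (-0.28, 0.46) were not called.

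In mock roots, 50 mM NaCl raised genes such as EXT2, NRT2.1 and KIN1. The extensin gene EXT2 rose 26.8-fold to 99.1 ± 55.3 FPKM from 2.60 ± 1.63. EARLI1, which codes for a lipid transfer type protein, rose 19.2-fold to 265 ± 69.1 FPKM from 13.03 ± 4.099. The cold and ABA gene KIN1 rose 17.1-fold to 284 ± 136 FPKM from 15.1 ± 5.98. The peroxidase gene PER35 rose 16.2-fold (40.4 ± 17.8 against 1.43 ± 0.453 FPKM). The root hair genes PRP3 and EXPA7 rose 15.0-fold (86.0 ± 52.8 against 4.25 ± 1.22 FPKM) and 11.7-fold (48.8 ± 18.3 against 3.18 ± 1.34 FPKM). NRT2.1 rose 7.06-fold to 1007 ± 545 FPKM from 135 ± 52.3, and its partner NRT3.1 rose 5.21-fold to 509 ± 193 FPKM from 94.2 ± 22.5. The sodium exporter gene SOS1 rose 2.13-fold to 13.7 ± 1.34 FPKM from 5.88 ± 0.624. COR15A rose 5.43-fold to 10.9 ± 6.65 FPKM from 0.980 ± 0.223. ALD1, of the pipecolate pathway, was listed at 0 in all 3 mock 0 mM libraries and at 2.86 ± 0.414 FPKM with salt. The dirigent gene DIR5 fell 11.2-fold to 0.487 ± 0.170 FPKM from 17.9 ± 11.98. UMAMIT17, an amino acid transporter gene, fell 9.46-fold to 7.59 ± 2.21 FPKM from 79.1 ± 11.3. CYP79B3, which feeds indole glucosinolates and camalexin, fell 5.17-fold to 17.1 ± 9.42 FPKM from 85.4 ± 9.13. PAD3 rose 4.85-fold (13.04 ± 0.968 against 2.08 ± 1.26 FPKM) while MYB51 fell 3.49-fold (log2 -1.80, standard error 0.22). RD29A did not pass (log2 2.4, standard error 0.92, adjusted p = 0.0723). In limma 5645 of 19651 genes passed (3319 up, 2326 down; 1530 by at least 2-fold), and after quantile normalization the split was 2798 up and 2743 down. The count was 11083 with library weights and 3472 without mock 0 mM replicate 3.

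By list, 4 of 5 root hair genes rose with salt in mock roots, also 4 when adjusted over the list alone (median log2 3.09, camera adjusted p = 0.000558, and adjusted p = 0.441 with an estimated correlation). Nitrate genes had 5 of 10 up, 9 when adjusted over the list alone (median log2 1.61, adjusted p = 0.000549, 0.441 with an estimated correlation). Sulfur limitation genes had 5 of 7 up, 6 when adjusted over the list alone (median log2 1.46, adjusted p = 0.000522, 0.441 with an estimated correlation); the sulfate transporter gene SULTR1;2 (AT1G78000) rose 4.68-fold to 73.6 ± 1.63 FPKM from 15.0 ± 2.05. ABA and osmotic genes had 7 of 25 up and none down, the same adjusted over the list alone (median log2 0.87, adjusted p = 0.00387, 0.643 with an estimated correlation). Ion transport genes had 6 of 11 up, also 6 adjusted over the list alone (median log2 0.88, adjusted p = 0.0104, 0.441 with an estimated correlation). Iron deficiency genes had 6 up and 1 down of 18, 8 and 2 when adjusted over the list alone (median log2 0.61, adjusted p = 0.0275, 0.471 with an estimated correlation); NAS2, a nicotianamine synthase gene, rose 9.94-fold and the regulator gene FIT 6.13-fold. Photosynthesis genes had 9 of 28 up, also 9 adjusted over the list alone (median log2 0.72, adjusted p = 0.000408, 0.686 with an estimated correlation). Indole glucosinolate genes were called down, with 1 up and 4 down of 12, and 1 up and 5 down adjusted over the list alone (median log2 -0.54, adjusted p = 0.0208, 0.538 with an estimated correlation). Tryptophan and camalexin genes were not called (1 up, 4 down; median log2 -0.30, adjusted p = 0.0672), nor were phosphate starvation genes with 3 up and 3 down of 11 (-0.42, 0.641), hypoxia genes (0.18, 0.556) or suberin genes (0.60, 0.0981). For salicylate genes (3 up, 1 down of 12) the median was -0.01 and the mean 0.11, and immune genes (5 up, 1 down of 22) had a median of -0.14 with a test direction of up; neither was called.

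In K23 roots far fewer genes passed for salt. The labels of K23 replicate 1 at 0 and 50 mM may be exchanged, as described below, and the root comparisons with K23 rest on them. EARLI1 rose 18.9-fold to 123 ± 99.96 FPKM from 4.65 ± 2.42 (adjusted p = 0.00692). The chitinase gene AT2G43590 rose 7.88-fold to 332 ± 50.9 FPKM from 43.3 ± 17.8, and SULTR1;2 (AT1G78000) rose 2.38-fold (log2 1.25, standard error 0.19). RL2 (AT2G21650), a MYB-like gene, fell 7.06-fold to 0.957 ± 0.843 FPKM from 12.7 ± 5.62. The dirigent gene DIR14 fell 4.75-fold to 10.1 ± 1.16 FPKM from 54.2 ± 18.9. In limma 83 of 19651 genes passed (41 up, 42 down). With only the 2 groups in the fit none passed, and the adjusted p was 0.141 for EARLI1, AT2G43590 and DIR14 and 0.144 for RL2 (AT2G21650). The count was 46 with a pseudocount of 0.1, 51 for genes of mean FPKM of at least 5, 129 after quantile normalization, 2894 with library weights and 1191 without K23 0 mM replicate 1. It was 14 and 19 without K23 0 mM replicates 2 and 3, 39 and 13 without K23 50 mM replicates 2 and 3, 40, 44 and 39 without mock 0 mM replicates 1, 2 and 3, and 31 without mock 50 mM replicate 1. Tryptophan and camalexin genes rose in 3 of 18 cases, with 7 up and 1 down adjusted over the list alone (median log2 0.57, camera adjusted p = 2.42e-05, and adjusted p = 0.538 with an estimated correlation). Ion transport genes had 1 of 11 up, 5 when adjusted over the list alone (median log2 0.35, adjusted p = 0.00293, 0.441 with an estimated correlation). Iron deficiency genes had 0 of 18 passing, 5 up when adjusted over the list alone (median log2 0.45, adjusted p = 0.00618, 0.441 with an estimated correlation). Called up with 0 genes passing were senescence genes (4 of 9 up adjusted over the list alone; median log2 0.44, adjusted p = 0.00358, 0.441 with an estimated correlation), nitrate genes (3 of 10 up adjusted over the list alone; 0.46, 0.0274, 0.592 with an estimated correlation) and photosynthesis genes (0 of 28 adjusted over the list alone; 0.49, 0.000549, 0.694 with an estimated correlation).

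For the interaction of fungus and salt in roots, no gene of 19651 passed in limma and none with voom. The interaction too rests on the labels of K23 replicate 1 at 0 and 50 mM, which may be exchanged. At an unadjusted p under 0.05 there were 3238 genes (16.5%), and the smallest adjusted p was 0.0685. Members of the fixed lists with large estimates for their list included CYP71A13 (log2 2.38, adjusted p = 0.0864), MYB51 (2.04, 0.0735), PRP3 (-3.23, 0.0843), EXPA7 (-2.55, 0.0893), ICS1 (-1.32, 0.0774) and SEN1 (AT4G35770, 2.53, 0.0864). They were not ranked against all genes. The count was 1 with a pseudocount of 0.1, 5 without the filter, 4 after quantile normalization, 2252 with library weights, 56 without K23 0 mM replicate 1, 85 without mock 50 mM replicate 2, 3 and 2 without K23 50 mM replicates 1 and 3, and 1 without mock 0 mM replicate 1. Camera called 8 lists, in none of which a gene passed over all genes. Tryptophan and camalexin genes were called up (median log2 1.06, 8 of 18 up adjusted over the list alone, adjusted p = 3.08e-08, and adjusted p = 0.441 with an estimated correlation). In this list 17 estimates were positive and 1 negative, that of PAD3, whose fold with K23 was smaller at 50 mM than at 0 mM. Also called up were indole glucosinolate genes (median log2 0.66, 6 up and 1 down of 12 adjusted over the list alone, adjusted p = 0.00167, 0.441 with an estimated correlation) and ethylene and jasmonate defence genes (median log2 0.99, 0 of 12 adjusted over the list alone, adjusted p = 0.0156, 0.581 with an estimated correlation). Root hair genes were called down (median log2 -2.04, 4 of 5 down adjusted over the list alone; adjusted p = 0.000302, 0.441 with an estimated correlation), and so were sulfur limitation genes (median log2 -0.94, 5 of 7 down adjusted over the list alone; adjusted p = 0.000807, 0.441 with an estimated correlation). Nitrate genes (median log2 -1.25, 0 of 10 adjusted over the list alone; adjusted p = 0.00523, 0.538 with an estimated correlation), ABA and osmotic genes (median log2 -0.78, 0 of 25 adjusted over the list alone; adjusted p = 0.0113, 0.694 with an estimated correlation) and suberin genes (median log2 -0.71, 0 of 11 adjusted over the list alone; adjusted p = 0.043, 0.696 with an estimated correlation) were the remaining calls.

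Across genes, the root response to K23 at 0 mM correlated with that at 50 mM at r = 0.369 (Spearman 0.21), with 270 genes up in both against 25.2 by chance, 41 down in both against 6.58, and 3 in opposite directions against 26.0. CYP71A12, PAD3, FOX1, CYP81F2 and IGMT2 were among those up in both. The root salt responses of mock and K23 plants correlated at r = 0.563 (Spearman 0.533), with 33 genes such as EARLI1 up in both against 6.92 by chance and 32 down in both against 4.97. These pairs of comparisons share no library. Comparisons within a tissue share each gene's estimate of spread, whereas the chance counts take their calls as independent, so those counts can be too low. The mean fungus and mean salt effects in roots correlated at r = 0.229 (Spearman 0.295), with 447 genes up for both against 191 by chance, 193 down for both against 81.1, and 185 in opposite directions against 250. Both effects come from the same 12 libraries. Unchanged groups were simulated 1000 times from the deviations within groups. There r had a median of -0.235 and lay between -0.9 and 0.78 in 95%, with 748 as far from 0 as the observed value. The observed r also holds the called changes, which the simulations lack, so they cannot judge it. This r alone therefore neither shows nor excludes a shared response (covariance 0.0383 against a simulated mean of -0.00983, whose spread was not taken). Genes are not independent of each other, so no p-value is given for these correlations; the first ranged from 0.249 to 0.472 over left-out libraries and the last from 0.099 (without K23 0 mM replicate 1) to 0.295.

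In shoots, the clock genes CCA1, PRR9, LHY and RVE8 and the light-signalling genes HYH and BIC2 were lower with K23 at 0 mM. CCA1, a morning clock gene, fell 26.6-fold to 1.61 ± 1.80 FPKM from 64.0 ± 28.1 (log2 -4.73, standard error 0.42, adjusted p = 0.000143). PRR9 fell 15.8-fold to 2.34 ± 3.16 FPKM from 41.3 ± 16.2. LHY fell 8.94-fold and RVE8 8.57-fold. HYH, a bZIP gene, fell 11.5-fold to 2.51 ± 0.864 FPKM from 38.9 ± 6.001. BIC2, an inhibitor of cryptochromes, fell 11.8-fold. COR27, an evening gene, rose 16.7-fold to 67.4 ± 40.2 FPKM from 3.02 ± 2.83. The evening clock gene ELF4 rose 8.02-fold to 65.0 ± 34.3 FPKM from 7.54 ± 5.83. VSP1, a jasmonate-responsive storage protein gene, rose 9.87-fold to 180.0 ± 95.3 FPKM from 16.3 ± 4.62. AOS of jasmonate synthesis fell 3.82-fold to 53.0 ± 19.9 FPKM from 206 ± 88.4. PR1, a salicylate marker gene, rose 5.67-fold to 586 ± 215 FPKM from 110.2 ± 67.3 (adjusted p = 0.00969). LTP12 was listed at 0 in all 3 mock libraries and at 10.01 ± 7.003 FPKM with K23. The nitrate reductase gene NIA2 fell 2.97-fold (164 ± 35.7 against 490.1 ± 104 FPKM), the nitrilase gene NIT1 3.55-fold (234 ± 16.4 against 837 ± 99.7 FPKM) and CYP79F1 of aliphatic glucosinolate synthesis 4.67-fold (1.39 ± 0.588 against 9.95 ± 0.817 FPKM). PDF1.2 (log2 -1.60, standard error 0.77, adjusted p = 0.187), PAD3 (-0.02, 0.61, 0.984) and GH3.3 (-1.24, adjusted p = 0.178) did not pass. In limma 2766 of 19055 genes passed (1336 up, 1430 down; 1053 by at least 2-fold), and after quantile normalization the split was 1605 up and 1305 down. The count was 1354 with only the 2 groups, 4179 with library weights, 1282 and 1717 without K23 0 mM replicates 1 and 3, and 1141 and 1393 without mock 0 mM replicates 2 and 3.

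**Figure D2:**
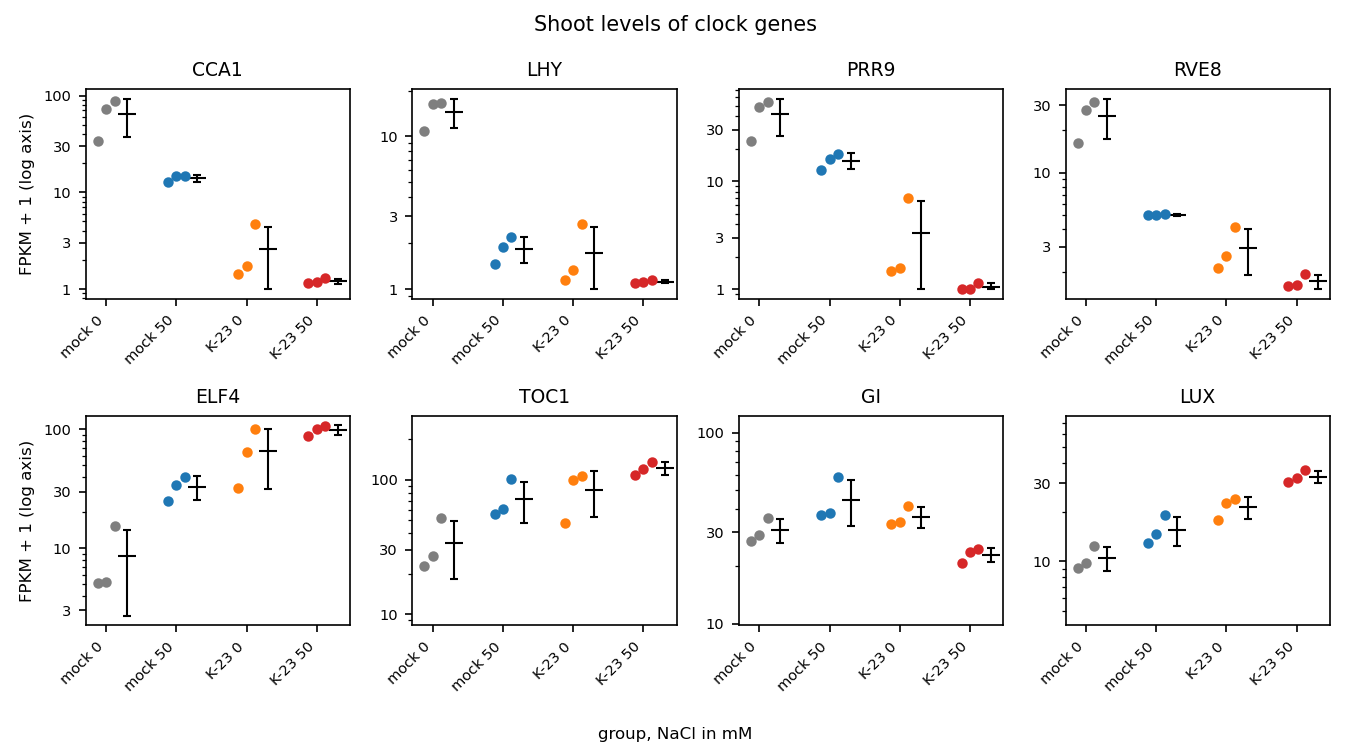
Clock genes in shoots, 4 groups on the horizontal axis and FPKM + 1 on a logarithmic vertical axis, 3 libraries per group; dash and bar give mean ± SD, with the lower end at 0 FPKM where the SD exceeds the mean. CCA1 was at 64.0 ± 28.1 FPKM in mock shoots and 1.61 ± 1.80 FPKM with K23 at 0 mM NaCl.

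Of 13 aliphatic glucosinolate genes, 7 fell and none rose in K23 shoots at 0 mM, also 7 when adjusted over the list alone (median log2 -1.26, camera adjusted p = 6.91e-07, and adjusted p = 0.522 with an estimated correlation). The regulator gene MYB29 fell 3.93-fold to 0.721 ± 0.247 FPKM from 5.75 ± 0.783. Photosynthesis genes were called down although 0 of 28 passed, also 0 adjusted over the list alone (median log2 -0.70, adjusted p = 1.48e-05, 0.869 with an estimated correlation). Hypoxia genes had 4 of 10 up, 6 when adjusted over the list alone (median log2 0.96, adjusted p = 0.00226, 0.683 with an estimated correlation). The oxygen sensor gene PCO1 rose 3.27-fold to 14.8 ± 4.08 FPKM from 3.74 ± 0.282. Phosphate starvation genes had 2 of 8 up, also 2 adjusted over the list alone (median log2 0.73, adjusted p = 0.0184, 0.824 with an estimated correlation). Oxidative detoxification genes had 3 of 8 down, also 3 adjusted over the list alone (median log2 -0.57, adjusted p = 0.0402, 0.522 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.149). The circadian list had 3 up and 5 down of 10 genes and was not called (median log2 -0.49, adjusted p = 0.155). Of 9 further morning output genes outside the lists 8 fell (median log2 -2.73), and all 6 further evening genes rose (median log2 1.76). Jasmonate genes (1 up, 1 down of 21; median log2 -1.08, adjusted p = 0.176), ABA and osmotic genes (1 up, 3 down of 26; -0.31, 0.183), salicylate genes (2 up of 17; 0.30, 0.236) and immune genes (2 down of 22; -0.28, 0.367) were not called. Tryptophan and camalexin genes had a median of -0.05 but a mean of 0.23 and were not called (2 of 18 up, adjusted p = 0.588); reference genes had 0 of 8 passing (median log2 -0.19, adjusted p = 0.197).

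At 50 mM NaCl, K23 shoots held less transcript of genes such as COR15A, NCED3 and KIN1 than mock shoots. COR15A, a cold and drought gene, fell 22.0-fold to 15.3 ± 3.098 FPKM from 388 ± 186 (log2 -4.46, standard error 0.45, adjusted p = 9.98e-05). NCED3, the rate-limiting gene of ABA synthesis, fell 18.5-fold to 5.41 ± 2.07 FPKM from 124 ± 69.7. KIN1 fell 16.9-fold to 1.12 ± 0.465 FPKM from 38.0 ± 22.6. RD29A fell 10.04-fold to 44.1 ± 8.66 FPKM from 584 ± 542. The vacuolar ion exchanger gene NHX2 fell 3.83-fold to 4.27 ± 0.364 FPKM from 19.3 ± 2.81. The ubiquitin ligase gene PUB19 fell 37.4-fold to 7.05 ± 4.25 FPKM from 305 ± 207. DREB1A fell 19.3-fold to 1.49 ± 0.195 FPKM from 49.2 ± 18.4. Light-harvesting genes fell as well, LHCB2.1 by 23.6-fold to 97.4 ± 14.1 FPKM from 2330.4 ± 383, and LHCB2.2 by 11.7-fold to 204 ± 20.2 FPKM from 2409.7 ± 407, although reads of these near-identical genes may be shared. The proline dehydrogenase gene POX1 rose 45.6-fold to 235 ± 42.4 FPKM from 4.19 ± 1.02 (adjusted p = 2.21e-06). XTH25 rose 29.7-fold (68.6 ± 6.08 against 1.37 ± 0.465 FPKM), MIOX2, an inositol oxygenase gene, 21.9-fold (68.3 ± 24.3 against 2.06 ± 0.310 FPKM), BCAT2 21.7-fold (153 ± 37.6 against 5.98 ± 0.868 FPKM) and the sugar starvation gene DIN10 19.5-fold (529.6 ± 12.3 against 26.2 ± 0.868 FPKM). SEN1 (AT4G35770) rose 18.9-fold to 1385 ± 370 FPKM from 71.0 ± 11.7. The asparagine synthetase gene ASN1 rose 11.5-fold to 557 ± 153 FPKM from 46.3 ± 5.42. PR1 rose 5.33-fold to 89.99 ± 43.9 FPKM from 16.4 ± 7.86. NIT2 rose 11.2-fold to 77.1 ± 50.4 FPKM from 5.31 ± 1.93. CCA1 fell 11.6-fold to 0.207 ± 0.0703 FPKM from 12.99 ± 1.12. PDF1.2 (log2 -0.63, adjusted p = 0.608) and PAD3 (1.09, 0.229) did not pass. In limma 4189 of 19055 genes passed (1916 up, 2273 down; 529 and 1231 by at least 2-fold), and after quantile normalization the split was 2520 up and 1875 down. The count was 2788 and 2622 without K23 50 mM replicates 1 and 2.

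**Figure D3:**
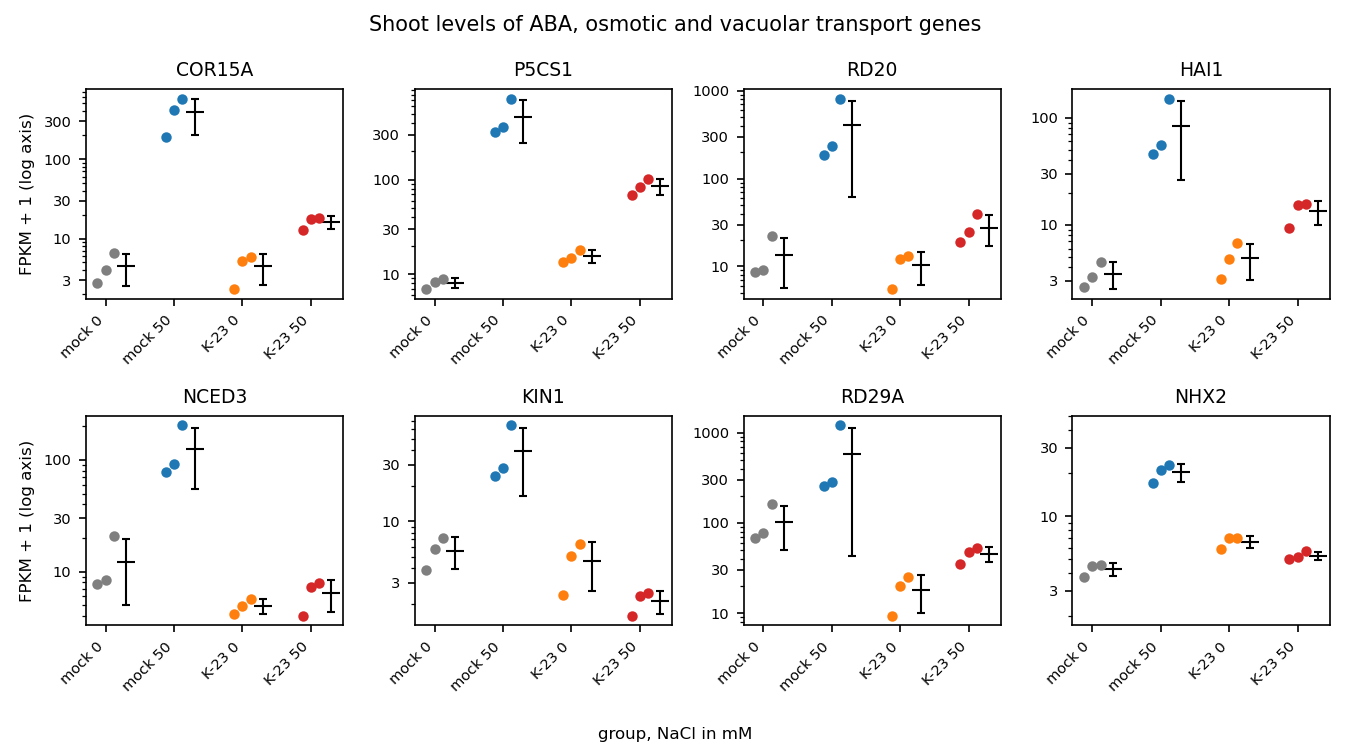
ABA, osmotic and ion transport genes in shoots, 4 groups on the horizontal axis and FPKM + 1 on a logarithmic vertical axis, 3 libraries per group; dash and bar give mean ± SD, with the lower end at 0 FPKM where the SD exceeds the mean. COR15A was at 388 ± 186 FPKM in mock shoots with 50 mM NaCl and 15.3 ± 3.098 FPKM with K23 and 50 mM NaCl.

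Of 26 ABA and osmotic genes 21 fell and none rose in K23 shoots at 50 mM, 23 when adjusted over the list alone (median log2 -2.13, camera adjusted p = 6.61e-14, and adjusted p = 0.522 with an estimated correlation). Photosynthesis genes had 14 of 28 down, 23 when adjusted over the list alone (median log2 -0.99, adjusted p = 1.42e-07, 0.824 with an estimated correlation). Auxin response genes had 7 of 13 down, 9 when adjusted over the list alone (median log2 -1.44, adjusted p = 0.000847, 0.664 with an estimated correlation). IAA1 fell 4.59-fold to 7.83 ± 1.83 FPKM from 39.4 ± 8.15. Jasmonate genes had 1 up and 7 down of 21, 1 and 9 when adjusted over the list alone (median log2 -1.19, adjusted p = 0.0121, 0.944 with an estimated correlation). The repressor gene JAZ1 fell 5.08-fold to 58.2 ± 9.91 FPKM from 314 ± 133. Aliphatic glucosinolate genes had 7 of 13 down, 10 when adjusted over the list alone (median log2 -0.79, adjusted p = 0.000134, 0.664 with an estimated correlation), with MYB29 down 4.68-fold (2.501 ± 0.568 against 15.3 ± 1.48 FPKM). Indole glucosinolate genes had 4 of 12 down, also 4 adjusted over the list alone (median log2 -0.88, adjusted p = 0.00234, 0.824 with an estimated correlation), with MYB34 down 4.40-fold. The circadian list had 2 up and 6 down of 10, 3 and 7 when adjusted over the list alone (median log2 -1.03, adjusted p = 0.0482, 0.664 with an estimated correlation), while 9 further morning output genes had a median log2 of -2.01 and 6 evening genes one of 1.34. Senescence genes had 3 up and 1 down of 9, 4 and 1 when adjusted over the list alone (median log2 0.68, adjusted p = 0.0491, 0.824 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.0665). Ethylene and jasmonate defence genes (1 up, 4 down of 17; -0.61, adjusted p = 0.333), salicylate genes (1 up, 4 down of 17; -0.39, 0.668), immune genes (3 down of 22; -0.49, 0.0913) and hypoxia genes (1 up of 10; 0.06, 0.908) were not called. Ion transport genes had a median of 0.05 but a mean of -0.11 and were not called (2 up, 1 down of 8, adjusted p = 0.992).

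In mock shoots, salt raised genes such as COR15A, P5CS1 and COR15B. COR15A rose 84.3-fold to 388 ± 186 FPKM from 3.49 ± 1.99 (log2 6.40, standard error 0.45, adjusted p = 1.16e-05). P5CS1 of proline synthesis rose 54.8-fold to 468 ± 225 FPKM from 7.03 ± 0.972. COR15B rose 45.9-fold to 206 ± 71.9 FPKM from 3.47 ± 1.38. RD20 rose 27.3-fold to 412 ± 351 FPKM from 12.3 ± 7.73, the phosphatase gene HAI1 21.5-fold to 83.4 ± 58.0 FPKM from 2.49 ± 0.970, RD29B 6.50-fold (log2 2.70, standard error 0.49) and NHX2 4.75-fold to 19.3 ± 2.81 FPKM from 3.26 ± 0.424. EARLI1 fell 123-fold to 1.77 ± 0.543 FPKM from 477 ± 470.4. The desaturase gene SAD6 fell 57.5-fold to 0.136 ± 0.236 FPKM from 64.4 ± 12.98. POX1 fell 26.8-fold to 4.19 ± 1.02 FPKM from 148 ± 77.7. AZI1, needed for azelaic acid priming, fell 25.9-fold to 25.4 ± 1.498 FPKM from 742 ± 369. PAD3 fell 10.2-fold to 3.81 ± 2.08 FPKM from 54.9 ± 41.8. PR1 fell 6.18-fold to 16.4 ± 7.86 FPKM from 110.2 ± 67.3. SEN1 (AT4G35770) fell 8.03-fold to 71.0 ± 11.7 FPKM from 575 ± 58.2. The alcohol dehydrogenase gene ADH1 fell 8.10-fold to 3.89 ± 1.24 FPKM from 38.0 ± 4.86. LHY and CCA1 fell 7.89-fold and 4.31-fold. In limma 5178 of 19055 genes passed (2891 up, 2287 down; 1858 by at least 2-fold), and with median-of-ratios scaling the split was 2559 up and 2602 down. The count was 8055 with library weights and 3403 without mock 0 mM replicate 2.

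Of 26 ABA and osmotic genes 22 rose with salt in mock shoots and none fell, also 22 when adjusted over the list alone (median log2 2.70, camera adjusted p = 3.14e-13, and adjusted p = 0.522 with an estimated correlation). Defence lists were called down. Salicylate genes had 12 of 17 down, 13 when adjusted over the list alone (median log2 -1.36, adjusted p = 5.81e-06, 0.664 with an estimated correlation). Tryptophan and camalexin genes had 10 of 18 down, 11 when adjusted over the list alone (median log2 -1.11, adjusted p = 0.000238, 0.824 with an estimated correlation). Immune genes had 5 of 22 down, also 5 adjusted over the list alone (median log2 -0.80, adjusted p = 0.00234, 0.869 with an estimated correlation). Ethylene and jasmonate defence genes had 6 of 17 down, also 6 adjusted over the list alone (median log2 -1.03, adjusted p = 0.000682, 0.522 with an estimated correlation). Hypoxia genes had 7 of 10 down, 8 when adjusted over the list alone (median log2 -1.23, adjusted p = 5.81e-06, 0.57 with an estimated correlation). Photosynthesis genes had 7 of 28 up, also 7 adjusted over the list alone (median log2 0.66, adjusted p = 0.000661, 0.944 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.525). Jasmonate genes (3 up of 21; 0.50, adjusted p = 0.132), aliphatic glucosinolate genes (3 up of 13; 0.41, 0.0522), nitrate genes (5 down of 9; -0.95, 0.0913), senescence genes (1 up, 4 down of 9; -1.07, 0.223), auxin response genes (2 up of 13; 0.17, 0.575) and the circadian list (3 up, 3 down of 10; -0.25, 0.425) were not called. The further morning output genes had a median log2 of -0.98 and the evening genes one of 1.34. Ion transport genes had 2 up and 3 down of 8, a median of -0.02 and a mean of 0.10, and were not called (adjusted p = 0.994).

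In K23 shoots, salt raised 8 of 26 ABA and osmotic genes and lowered defence genes such as PR1 and PR5. P5CS1 rose 5.50-fold to 84.5 ± 16.4 FPKM from 14.5 ± 2.36 and RAB18 4.78-fold (log2 2.26, standard error 0.34). The histone gene HIS1-3 rose 10.4-fold to 118 ± 29.7 FPKM from 11.3 ± 6.47. VSP2, a jasmonate-responsive gene, rose 7.68-fold to 294 ± 107 FPKM from 37.7 ± 15.2. SAD6 fell 64.6-fold to 0.164 ± 0.285 FPKM from 80.0 ± 44.3, EARLI1 22.5-fold to 4.11 ± 2.56 FPKM from 108 ± 28.3, the glucanase gene BG3 18.0-fold to 1.87 ± 0.882 FPKM from 56.2 ± 37.3, and the haemoglobin gene HB1 15.3-fold to 2.76 ± 0.282 FPKM from 58.8 ± 21.9. PR5 fell 8.57-fold to 24.8 ± 12.6 FPKM from 204 ± 25.3, PR1 6.57-fold to 89.99 ± 43.9 FPKM from 586 ± 215, and MYB51 4.57-fold to 23.6 ± 2.86 FPKM from 111 ± 7.71. PDF1.2 (log2 -1.94, adjusted p = 0.109), RD29A (1.41, 0.114) and RD29B (0.64, 0.406) did not pass. In limma 3072 of 19055 genes passed (1697 up, 1375 down; 1242 by at least 2-fold). The count was 1731 and 1732 without K23 0 mM replicates 1 and 3, and 1033 and 1634 without K23 50 mM replicates 1 and 3. Hypoxia genes had 9 of 10 down, all 10 when adjusted over the list alone (median log2 -2.54, camera adjusted p = 3.21e-12, and adjusted p = 0.522 with an estimated correlation). Salicylate genes had 14 of 17 down, 16 when adjusted over the list alone (median log2 -1.88, adjusted p = 1.5e-11, 0.522 with an estimated correlation). Tryptophan and camalexin genes had 12 of 18 down, 16 when adjusted over the list alone (median log2 -1.37, adjusted p = 1.27e-08, 0.664 with an estimated correlation). Immune genes had 5 of 22 down, 11 when adjusted over the list alone (median log2 -1.17, adjusted p = 9.08e-07, 0.664 with an estimated correlation). Indole glucosinolate genes had 1 up and 7 down of 12, 1 and 9 when adjusted over the list alone (median log2 -1.27, adjusted p = 5.89e-05, 0.664 with an estimated correlation). Ethylene and jasmonate defence genes had 5 of 17 down, 6 when adjusted over the list alone (median log2 -0.89, adjusted p = 0.000102, 0.522 with an estimated correlation). Nitrate genes had 5 of 9 down, 6 when adjusted over the list alone (median log2 -1.02, adjusted p = 0.00295, 0.613 with an estimated correlation). Called up were aliphatic glucosinolate genes (8 up and 1 down of 13, 10 and 1 adjusted over the list alone; median log2 1.03, adjusted p = 0.000661, 0.664 with an estimated correlation) and ABA and osmotic genes (8 up and 1 down of 26, 10 and 2 adjusted over the list alone; median log2 0.74, adjusted p = 0.00268, 0.869 with an estimated correlation).

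For the interaction of fungus and salt in shoots, POX1 (TAIR10 chromosome 3, 12448636 to 12451556) had an estimate of log2 5.30 (standard error 0.42, adjusted p = 0.000114), with 159 and 148 FPKM in K23 and mock shoots at 0 mM and 235 and 4.19 FPKM at 50 mM. MIOX2 (log2 5.07, standard error 0.35) stood at 33.6 against 53.9 FPKM without salt and 68.3 against 2.06 FPKM with salt, and RVE2, a MYB-like gene linked to the clock (log2 5.07, standard error 0.56), at 8.25 against 22.9 and 52.2 against 3.93 FPKM. SEN1 (AT4G35770, log2 4.67, standard error 0.35) and ASN1 (4.0, 0.34) had the same sign, as had AT1G62510 (4.97, 0.48), which codes for a lipid transfer type protein. In the other direction, COR15B (log2 -4.72, standard error 0.45), COR15A (TAIR10 chromosome 2, 17710441 to 17712330; -4.44, 0.64), KIN1 (-3.73, 0.61), P5CS1 (-3.32, 0.38), LEA7 (-3.32, 0.34), NAP (-2.78, 0.33) and NHX2 (-2.57, 0.20) had negative estimates. NHX2 went from 3.26 to 19.3 FPKM with salt in mock shoots and from 5.61 to 4.27 FPKM in K23 shoots. COR15A was at 3.49 FPKM in both groups at 0 mM and at 15.3 against 388 FPKM at 50 mM. PR1 (-0.09, standard error 0.72, adjusted p = 0.957) and PAD3 (1.12, adjusted p = 0.463) did not pass. In limma 1253 of 19055 genes passed (695 up, 558 down); the count was 2819 with library weights, 773, 2016 and 679 without K23 0 mM replicates 1, 2 and 3, 533, 581 and 724 without K23 50 mM replicates 1, 2 and 3, 440 and 775 without mock 0 mM replicates 2 and 3, and 769 without mock 50 mM replicate 1. ABA and osmotic genes had 13 of 26 down and none up, 18 when adjusted over the list alone (median log2 -1.77, camera adjusted p = 2.5e-11, and adjusted p = 0.57 with an estimated correlation). Hypoxia genes had 1 of 10 down, 3 when adjusted over the list alone (median log2 -0.83, adjusted p = 0.0136, 0.824 with an estimated correlation). Auxin response genes had 1 of 13 down, also 1 adjusted over the list alone (median log2 -0.98, adjusted p = 0.0491, 0.869 with an estimated correlation). Indole glucosinolate genes had 0 of 12 passing, also 0 adjusted over the list alone (median log2 -0.71, adjusted p = 0.0232, 0.883 with an estimated correlation).

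**Figure D4:**
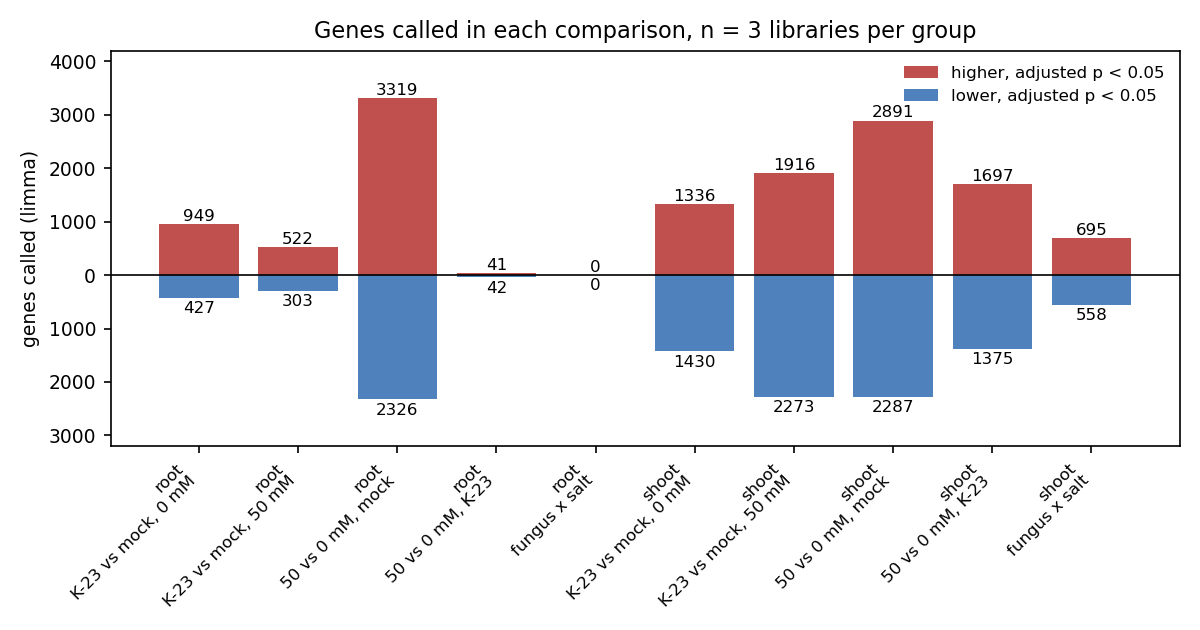
Genes up and down per comparison (limma, adjusted p under 0.05; 3 libraries per group), comparisons on one axis and number of genes on the other, without error bars. The counts range from 0 for the root interaction to 5645 for salt in mock roots.

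**Figure D5:**
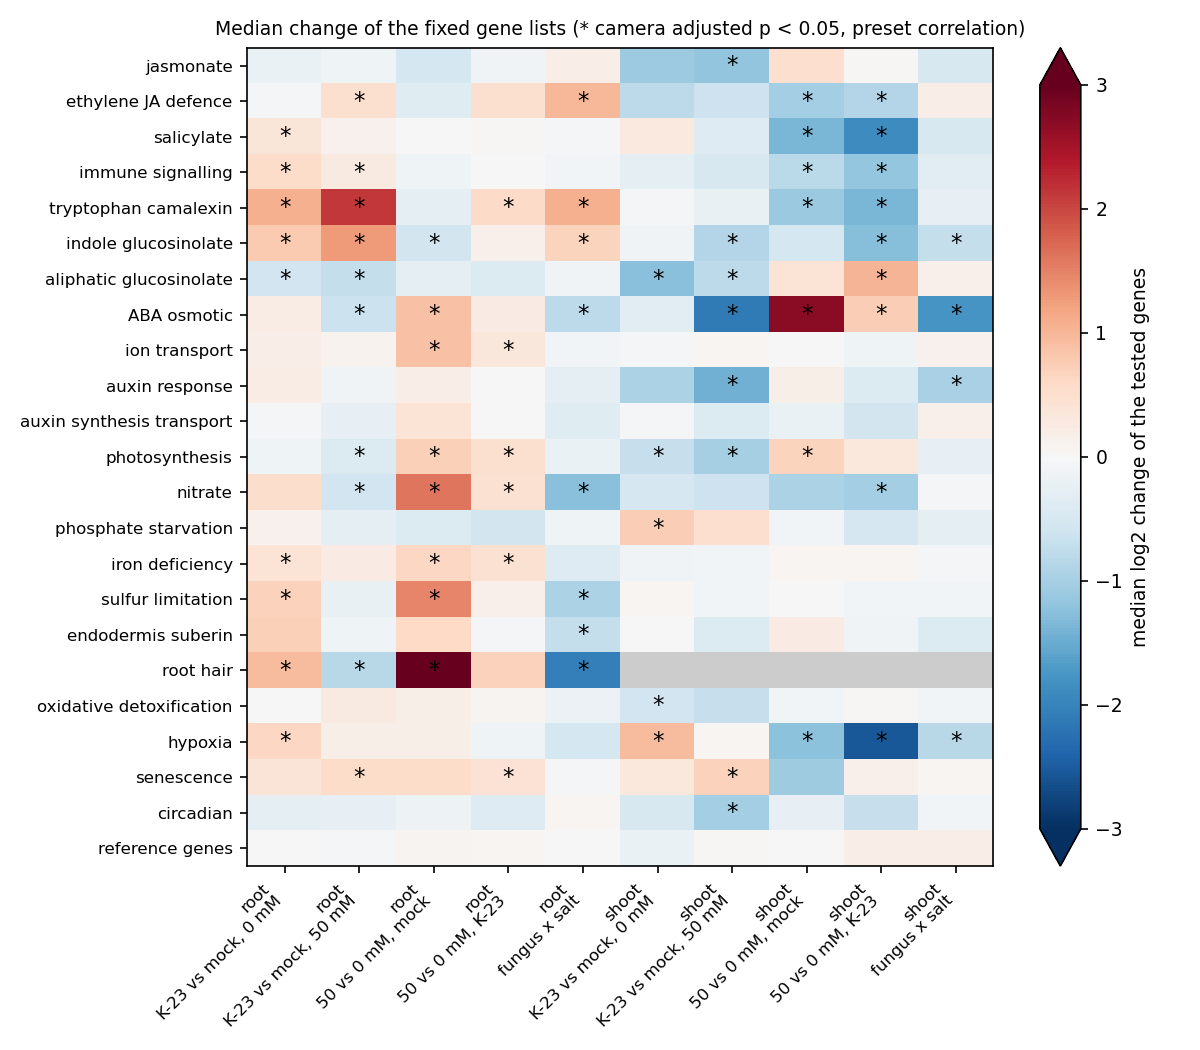
Median log2 change of each gene list (vertical axis) in each comparison (horizontal axis), 3 libraries per group and no error bars; an asterisk marks a camera adjusted p under 0.05, colours end at -3 and 3, and grey marks a list not tested. The ABA and osmotic list had a median of 2.70 with salt in mock shoots and of -2.13 with K23 at 50 mM.

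Across genes, the shoot response to K23 at 0 mM correlated with that at 50 mM at r = 0.484 (Spearman 0.386), with 336 genes up in both against 134 by chance, 641 down in both against 171, and 90 in opposite directions against 303. COR27 rose and CCA1, PRR9, MYB29 and NIA2 fell in both. The salt responses of mock and K23 shoots correlated at r = 0.519 (Spearman 0.406), with 712 genes such as P5CS1 up in both against 257 by chance and 647 such as SAD6 and PR1 down in both against 165. The mean fungus and mean salt effects in shoots correlated at r = 0.011 (Spearman 0.041), with 628 genes up for both against 437 by chance, 480 down for both against 413, and 1079 in opposite directions against 867. All of these counts lay above chance, in opposite as well as in the same directions, so the excess does not show a shared direction. The r of the mean effects ranged from -0.052 to 0.062 over left-out libraries. In simulations of unchanged groups, which as in roots cannot judge the observed r, it had a median of -0.272 and lay between -0.9 and 0.72 in 95% (covariance 0.00337 against -0.00817). Between tissues, the difference in the K23 response at 0 mM passed for 2224 of 17618 genes (1195 higher in roots, 1029 higher in shoots), at 50 mM for 1344 (773 and 571), and the difference in the salt response of mock plants for 5251 (2671 and 2580). EARLI1 rose with salt in mock roots and fell in mock shoots, while COR15A rose in both. At 50 mM, 125 genes rose with K23 in both tissues against 46.6 by chance and 131 fell in both against 30.6, with SEN1 (AT4G35770) up in both; the responses correlated at r = 0.328 (Spearman 0.34), against 0.15 (0.062) at 0 mM and 0.091 (0.053) for salt. The tissue counts at 0 mM, 50 mM and for salt were 4292, 3357 and 8744 with library weights; the first was 1297 without root mock 0 mM replicate 3 and 1364 and 1377 without shoot K23 0 mM replicates 1 and 3, and the second was 889 without root mock 50 mM replicate 1 and 895 without shoot K23 50 mM replicate 3.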

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

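All items here were picked by fixed rules after the data were seen, because a response differed between groups or tissues or because a gene or list departed most from equal responses; the tests on them were run after the result was seen. In shoots, 1253 genes passed for a fungus response that differed between 0 and 50 mM NaCl, against 0 in roots. These counts do not measure a difference between tissues, which was not tested for the interaction. At an unadjusted limma p under 0.05 the shares were 23.5% of genes in shoots and 16.5% in roots. Among 100 regroupings of the shoot libraries no other reached 1253, the highest being 623. These regroupings mix libraries across the fungus and salt groups, so the separate effects of fungus and salt enter the spread. They therefore cannot judge the interaction by itself. In roots the real count was 0, which all 100 regroupings reach whatever the data, so this comparison says nothing; the highest other gave 1145 genes. The response to K23 differed between tissues for 2224 genes at 0 mM and 1344 at 50 mM, and the response to salt in mock plants for 5251. Of 100 regroupings each, 2, 8 and 2 (the real one included) reached these counts, with highest others of 2594, 3926 and 5409. Libraries were regrouped within each tissue, so a regrouping can keep or reverse the true groups of a single tissue. It then still holds the real response of that tissue. These shares therefore do not measure how often a random grouping gives such counts.

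Genes with the largest shoot interaction, picked for size, were POX1 (log2 5.30), MIOX2 (5.07), RVE2 (5.07), AT1G62510 (4.97) and SEN1 (AT4G35770, 4.67) upward, and COR15B (-4.72), LHCB2.4 (-4.52), COR15A (-4.44), LTP3 (-4.37) and LTP4 (-4.03) downward. LHCB2.4 stood at 114 and 98.5 FPKM in K23 and mock shoots at 0 mM and at 21.2 and 754 FPKM at 50 mM; its call was lost without K23 50 mM replicate 2, K23 50 mM replicate 3 or mock 0 mM replicate 2, with an adjusted p of up to 0.0632. LTP3 (21.8 against 0.258 FPKM, then 17.5 against 31.4 FPKM) lost its call with voom (adjusted p = 0.108), and LTP4 in 9 alternatives (adjusted p up to 0.130). The others kept their calls in every alternative.

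Lists picked because their median interaction was called were, in roots, ethylene and jasmonate defence (median log2 0.99), tryptophan and camalexin (1.06), indole glucosinolate (0.66), ABA and osmotic (-0.78), nitrate (-1.25), sulfur limitation (-0.94), suberin (-0.71) and root hair genes (-2.04). In shoots they were indole glucosinolate (-0.71), ABA and osmotic (-1.77), auxin response (-0.98) and hypoxia genes (-0.83). None was called when the correlation between genes was estimated; in roots no single gene of these lists passed over all genes.

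For the simple comparisons only 10 splits of the 6 libraries exist, too few for a share under 0.05. The real grouping called the most genes in 7 of 8. Real and highest other counts were 1376 and 0 for K23 in roots at 0 mM, 825 and 0 at 50 mM, 5645 and 0 for salt in mock roots, 2766 and 210 for K23 in shoots at 0 mM, 4189 and 0 at 50 mM, 5178 and 1 for salt in mock shoots, and 3072 and 0 for salt in K23 shoots, with 1 split of 10 reaching the real count each time. For salt in K23 roots 2 of 10 reached the real 83, and another split called 1564 genes, many times the real count and a sign of structure among those 6 libraries. That split exchanges K23 0 mM replicate 1 with K23 50 mM replicate 1.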

How the results depend on the processing

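Voom, library weights for the 8 simple comparisons, left-out libraries of other groups, and left-out libraries for tissue comparisons and correlations were tests chosen after the result was seen; the rest were planned. Of the values that carry the text, 274 stayed the same under an alternative and 100 moved. The label allows a shift, since a count within a fixed ratio of the main one was called the same. For K23 in roots at 0 mM, 931 with a replicate block against 1376 was labelled the same. A correlation was labelled the same within the SD of its left-out values. Of the other values, which pool named genes, list calls and counts for mean effects, 11311 stayed, 1337 became weaker, 21 stronger and 7 moved. The 7 were all counts for mean effects, and no named gene reversed. A gene stayed when its call, or lack of one, did not change. Beyond fewer samples, what causes a shift was not tested.

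With library weights the counts were: root K23 at 0 mM 5296, at 50 mM 3338, salt in mock roots 11083, salt in K23 roots 2894, root interaction 2252, shoot K23 at 0 mM 4179 and at 50 mM 5372, salt in mock shoots 8055 and in K23 shoots 3035, shoot interaction 2819, and tissue comparisons 4292, 3357 and 8744; in roots the weights gave a convergence warning. With only the 2 groups compared the counts were 781 and 525 for K23 in roots, 0 for salt in K23 roots and 1354 for K23 in shoots at 0 mM. Salt in K23 roots gave 46 with a pseudocount of 0.1, 51 at a mean of 5 FPKM, 129 after quantile normalization; the root interaction gave 1, 5 (no filter) and 4 (quantile). Voom gave 1190, 849, 5622, 74 and 0 in roots and 2777, 4002, 4807, 2945 and 1134 in shoots.

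Leaving out 1 library gave 295 to 1726 genes for K23 in roots at 0 mM (359 without K23 0 mM replicate 3; 589, 472 and 295 without mock 0 mM replicates 1, 2 and 3), 366 to 1286 at 50 mM (1286 without K23 0 mM replicate 1; 477 and 391 without K23 50 mM replicates 2 and 3; 366 without mock 50 mM replicate 1), 3472 to 6766 for salt in mock roots (3472 without mock 0 mM replicate 3) and 13 to 1191 for salt in K23 roots (1191, 14 and 19 without K23 0 mM replicates 1, 2 and 3; 39 and 13 without K23 50 mM replicates 2 and 3; 40, 44 and 39 without mock 0 mM replicates 1, 2 and 3; 31 without mock 50 mM replicate 1). The root interaction gave 0 to 85 (56 without K23 0 mM replicate 1; 85 without mock 50 mM replicate 2; 3 and 2 without K23 50 mM replicates 1 and 3; 1 without mock 0 mM replicate 1). In shoots it gave 1141 to 3507 for K23 at 0 mM (1282 and 1717 without K23 0 mM replicates 1 and 3; 1141 and 1393 without mock 0 mM replicates 2 and 3), 2622 to 5021 at 50 mM (2788 and 2622 without K23 50 mM replicates 1 and 2), 3403 to 6003 for salt in mock shoots (3403 without mock 0 mM replicate 2), 1033 to 3847 for salt in K23 shoots (1731 and 1732 without K23 0 mM replicates 1 and 3; 1033 and 1634 without K23 50 mM replicates 1 and 3) and 440 to 2016 for the interaction (773, 2016 and 679 without K23 0 mM replicates 1, 2 and 3; 533, 581 and 724 without K23 50 mM replicates 1, 2 and 3; 440 and 775 without mock 0 mM replicates 2 and 3; 769 without mock 50 mM replicate 1). Tissue counts ranged over 1297 to 3334 (1297 without root mock 0 mM replicate 3; 1364 and 1377 without shoot K23 0 mM replicates 1 and 3), 889 to 1359 (889 without root mock 50 mM replicate 1; 895 without shoot K23 50 mM replicate 3) and 4143 to 5193.

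Correlations between responses ranged over 0.249 to 0.472, 0.449 to 0.638 and 0.099 to 0.295 in roots and 0.43 to 0.522, 0.436 to 0.55 and -0.052 to 0.062 in shoots when a library was left out; at a mean of 5 FPKM the first shoot value was 0.533 and the last 0.047, and with a pseudocount of 0.1 the last was -0.035. Of 41 root and 33 shoot list calls, an estimated correlation kept 0, and fry kept 15 in roots and 22 in shoots. In roots fry gave 22 calls in all, some of them for lists that camera did not call. Among these was the control list of reference genes for salt in mock roots (2 of 8 up, fry adjusted p = 0.0256, camera adjusted p = 0.556).

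With the replicate number as a replicate block, counts were 931, 656, 4990, 35 and 0 in roots, 2304, 3873, 4796, 2595 and 863 in shoots, 1960, 1077 and 5023 between tissues, and lists 43 and 33, without the calls of suberin genes in the root interaction (adjusted p = 0.0525) and of senescence genes for K23 in shoots at 50 mM (0.0515). The numbers do not pair the samples: deviations of libraries with the same number correlated at -0.62 to 0.64 in roots and -0.25 to 0.24 in shoots, over 0.1 in 4 and 5 of 18 pairs. Calls of named genes kept in all alternatives were 20 of 48, 25 of 45, 59 of 82 and 0 of 16 in roots, 32 of 57, 53 of 83, 54 of 76 and 42 of 68 in shoots, and 13 of 27 for the shoot interaction.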

Other observations

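The tests of clock output genes were written before their result was seen; all other tests in this part were chosen after the result was seen. In shoots the mean of CCA1 stood at 64.0 FPKM in mock plants, 12.99 with salt, 1.61 with K23 and 0.207 with both, and that of RVE8 at 24.3, 4.05, 1.95 and 0.713 FPKM. The means of the evening genes JMJ30 (1.06, 6.41, 39.6 and 139 FPKM), BOA (0.978, 2.37, 5.89 and 13.9 FPKM) and RBG7 (774, 2113, 3810.2 and 6109 FPKM) rose in that order of groups, although single libraries of JMJ30 (4.303 to 68.94 FPKM with K23, 5.681 to 7.238 with salt) and BOA (1.846 to 8.702 and 1.755 to 2.732 FPKM) did not. The evening genes ADO3 (13.1, 39.4, 43.5 and 34.5 FPKM) and RBG8 (327.5, 301.0, 633.2 and 599.1 FPKM) broke the order, as did the morning genes CDF1 (18.5, 16.5, 1.68 and 3.15 FPKM), CDF2 (16.04, 5.23, 5.52 and 4.73 FPKM), CDF5 (1.22, 0.129, 0.699 and 0.958 FPKM) and RVE1 (14.8, 3.46, 2.05 and 2.08 FPKM).

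On a scale of the root salt response with mock 0 mM at 0 and mock 50 mM at 1, the 3 K23 roots without salt scored 0.45, 0.34 and 0.37, and those with salt 0.74, 0.64 and 0.84. The 1081 rising and 540 falling genes of the scale were picked on the mock libraries, which pulls other libraries toward the middle.

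The morning clock genes CCA1, LHY, PRR9 and RVE8 had lower means in colonised than in mock plants in both tissues. A later hour of harvest of the colonised plants would lower morning outputs against evening outputs, and the difference of their median fungus effects was -4.01 log2 in shoots (8 of 9 morning genes down, 6 of 6 evening genes up) and -2.01 in roots (6 of 8 down, but 0 of 6 up). A fungal effect on the clock itself would give the same values, and the labels do not hold the hour, so these accounts cannot be told apart here. A single shoot library does not account for it, since the median fungus effect of CCA1, LHY, PRR9 and RVE8 stayed at -2.99 or lower whichever library was left out (highest without K23 0 mM replicate 3). Shoot genes with a daily rhythm, such as LHCB2.1, SEN1 (AT4G35770) and ASN1, may owe part of their change to the hour as well. For salt, the same difference was -2.32 in mock shoots (4 of 9 morning genes down, 3 of 6 evening genes up). It was -0.85 in K23 shoots, -0.07 in mock roots and -0.80 in K23 roots. In mock shoots, salt and the hour of harvest therefore cannot be told apart for clock genes either.

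Replicate 1 of K23 roots at 0 mM stood apart, with correlations of 0.925 and 0.924 to replicates 2 and 3 against 0.986 between those, and so did, in shoots, K23 0 mM replicate 2 (0.947 and 0.927 against 0.981) and mock 0 mM replicate 1 (0.965 and 0.952 against 0.987), which were not examined further. Exchanged labels with K23 50 mM replicate 1 stay open: the salt scores differed in the labelled order by 0.29 (SD 0.09), which goes against an exchange, but the split that exchanges this pair called 1564 genes against 83, and their deviations correlated at -0.62. K23 0 mM replicate 1 also correlated more with K23 50 mM replicates 2 and 3 (0.967 and 0.952) than with its own group, and K23 50 mM replicate 1, on average only, slightly more with K23 0 mM replicates 2 and 3 (0.964 and 0.972) than with its own (0.959 and 0.966). All results that include K23 roots, among them K23 against mock and the root interaction, rest on these labels as given. Carried-over shoot tissue could raise shoot genes, and 95.2% of 62 shoot-abundant genes were higher in replicate 1, by a median 1.73% of their shoot level, but touch and wound genes would need a median shoot share of 50.5%. Wounding or handling remains open for 13 touch and wound genes such as JAZ7 (log2 4.99) and ZAT12 (3.44, list median 2.57, at percentile 100 of 10000 random lists). Random lists drew each gene separately, whereas genes of a real list can move together. The circadian and photosynthesis lists lay at extremes as well, so the percentile does not single out handling. Another hour of harvest remains open too. Circadian genes had a median of -0.55 (percentile 0.1), but that list mixes morning and evening genes, so its median does not measure the hour. The median of 0.74 of photosynthesis genes (percentile 100) is near the 0.73 of the shoot-abundant genes and does not separate the hour from carry-over.

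ABA and osmotic genes rose less with salt in colonised shoots, with a median interaction of -1.77 (camera adjusted p = 2.5e-11, and adjusted p = 0.57 with an estimated correlation). Scaling was argued against by a value of -1.61 after quantile normalization, and a single library by a highest value of -1.43, without mock 50 mM replicate 2. A higher level of these genes in colonised shoots before salt was argued against by the fungus effect at 0 mM, with a median of -0.31. The fungus shift of morning against evening clock outputs was larger at 0 mM (-4.48) than at 50 mM (-3.36), while this list moved by -0.31 and -2.13. These values cannot decide on the hour of harvest. Morning genes such as CCA1 were near 0 in K23 shoots at 50 mM (mean 0.207 FPKM), which limits the shift there. List genes such as COR15A and HAI1 were low in mock shoots without salt, which limits their fall at 0 mM. An effect of the hour and a weaker osmotic stress of colonised shoots both remain possible.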
